A study of Mus musculus with 6 samples.

How the data were processed

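RNA from Ba/F3 cells was hybridised to Affymetrix Mouse Genome 430 2.0 arrays, 1 array per sample, 3 control and 3 NCOR1-LYN samples. The deposited values are probe set intensities on a linear scale, which were made by the authors with MAS5 per the submitters' processing notes, with no version given in the sources used here. MAS5 summarises the probes of a probe set after a background and mismatch correction, so that signals of dim probe sets are noisy and their folds less certain. The values themselves show that every array had been scaled to a mean of 500 after trimming 2% of the probe sets at each end, and no detection calls were used here. Between 50.6 and 52.7% of the probe sets of an array lay below a signal of 64.

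Groups and replicate numbers were taken from the sample labels. Signals were used as log2(signal + 64), the offset being the power of 2 nearest to 10% of the trimmed mean, and no further scaling was applied. All fold changes are on this scale, which understates the change of dim genes. Of 45101 probe sets, 64 were control probe sets, 34945 had exactly 1 gene symbol in the platform annotation, 932 had several and 9160 had none there. Only those with exactly 1 symbol entered, which covered 18193 genes, of which 9010 had more than 1 probe set. Symbols were checked through their Entrez identifiers against gene names of the GRCm38.p6 assembly, and 0 changed. No genome build belongs to the array values, so no coordinates are given. Each gene was represented by its probe set with the highest mean, and genes below the 40th percentile of mean log2 values (a signal of about 47) were left out, which left 10916 genes. Some genes, among them parts of the fusion list, had no usable symbol and are not reported here.

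Genes were tested with limma (3.58.1, in R 4.3.3) by lmFit and eBayes with an intensity trend, all 6 arrays, no covariate, and Benjamini-Hochberg adjustment over the 10916 genes. The threshold was an adjusted p of 0.05, two-sided, and a log2 fold change of at least 1 for the count of 2-fold genes. Residual degrees of freedom were 4 without and 2 with the replicate block. Gene lists were tested with camera at its preset correlation of 0.01 in the 27 of 29 lists with at least 5 measured genes, adjusted over lists, and again with an estimated correlation and with fry. The lists covered SRC family and fusion genes, cytokine receptors, SRC kinase adaptors, targets of STAT5, ERK, FOXO, NF-kB, MYC, p53, ATF4, HIF1 and interferon, ER stress, heat shock, cell cycle phases, mitochondrial translation, oxidative phosphorylation, glycolysis, cholesterol and fatty acid synthesis, the BCL2 family, the NCOR and HDAC3 complex, and markers of B lymphoid, myeloid, mast, erythroid and megakaryocyte, T and NK cells and fibroblasts. The groups, tests, lists, listed alternatives and the rule for named genes were fixed before the data were examined. The rule took up to 12 genes with the largest rise and 12 with the largest fall among those past the threshold with groups that did not overlap, every measured gene of the SRC family and cytokine receptor lists, and for each other list up to 4 genes past the threshold or else the gene with the largest change. The first part of the rule gave 9 genes, and genes named outside the rule are said to be chosen after their values were seen where they are named.

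Replicate numbers were checked for pairing by correlating, across genes, the deviations of arrays from their group means. Genes are not independent replicates in such a correlation. Arrays of the same number correlated at 0.62, 0.41 and 0.44 for replicates 1, 2 and 3, all above the limit of 0.1, so the numbers were taken to pair the arrays. The labels state no shared day or batch. Replicates 2 and 3 were not told apart by the check, since control 2 correlated at 0.39 with NCOR1-LYN 3 and control 3 at 0.48 with NCOR1-LYN 2. Deviations from a group mean balance out, so with replicate 1 apart in both groups such values tend to be positive for either matching. The check therefore bears on replicate 1 and not on the pairing of replicates 2 and 3.

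The ratio of 3′ to 5′ signal of the beta-actin control probe sets was 1.21 ± 0.04 in controls and 1.19 ± 0.04 with NCOR1-LYN (SD, n = 3, exact permutation p = 0.5, two-sided), and that of Gapdh 0.71 ± 0.03 in both (exact permutation p = 1). The smallest p that 3 against 3 arrays allow is 0.1. The fits were tested on simulated data, in 10 runs with 200 of the 10916 genes changed and the replicate effects of these arrays. Each simulated change was the same in all pairs, and the spread of a gene was the same in all arrays. Changes that differ between pairs were not simulated. For NCOR1-LYN against control, the fit without a block recovered 0.6, 32 and 93.2% of changes of 1.5-, 2- and 4-fold with 0 false calls among 82.4 per run, and the blocked fit 66.6, 97.5 and 100% with 19.5 false calls among 195.5 per run, a larger share than the adjusted p of 0.05 aims at. Alternatives covered the offset, the filter, quantile normalization, median centring, the handling of several probe sets, the intensity trend, robust variances, array weights, the replicate block, the list test and leaving out each array. The array weights were 0.161 for control 1 and 0.209 for NCOR1-LYN 1, against 1.68 to 3.73 for the other arrays. The fit with array weights thus largely sets replicate 1 aside, much as leaving out both replicate 1 arrays does. Figures were drawn with matplotlib 3.10.9.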

Results

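Gene expression was measured in Ba/F3 cells, a mouse pro-B cell line that needs interleukin 3 for growth, carrying a doxycycline-inducible construct for NCOR1-LYN. The construct joins parts of NCOR1, a nuclear receptor corepressor, and of LYN, a tyrosine kinase of the SRC family. The series held 6 Affymetrix Mouse Genome 430 2.0 arrays, 3 of uninduced control cells and 3 of cells given doxycycline to switch on NCOR1-LYN. Expression of the fusion itself was not followed on these arrays, so its induction was not checked here. The labels speak of triplicate cultures and say nothing more on how far the replicates were independent, so p-values measure the spread between these arrays. Doxycycline was given to all NCOR1-LYN cultures and to no control culture, so the drug and the fusion protein cannot be told apart, and cells given doxycycline without the construct were not analysed here. Median signals ran from 54.6 to 61.7 after the authors' scaling of each array, and the number of arrays limits the precision.

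Replicate 1 of both groups lay apart from replicates 2 and 3. The first principal component of the 10916 genes tested held 58% of the variance and placed the replicate 1 arrays at −37.2 (control) and −24.9 (NCOR1-LYN), against 12 to 18.6 for the other 4 arrays. The second component held 20.2% of the variance and parted the groups, with the controls at −15.5 to −9.8 and the NCOR1-LYN arrays at 6.1 to 22.3. Values from the fit with the replicate number as a block are therefore given beside those from the fit without it.

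**Figure D1:**
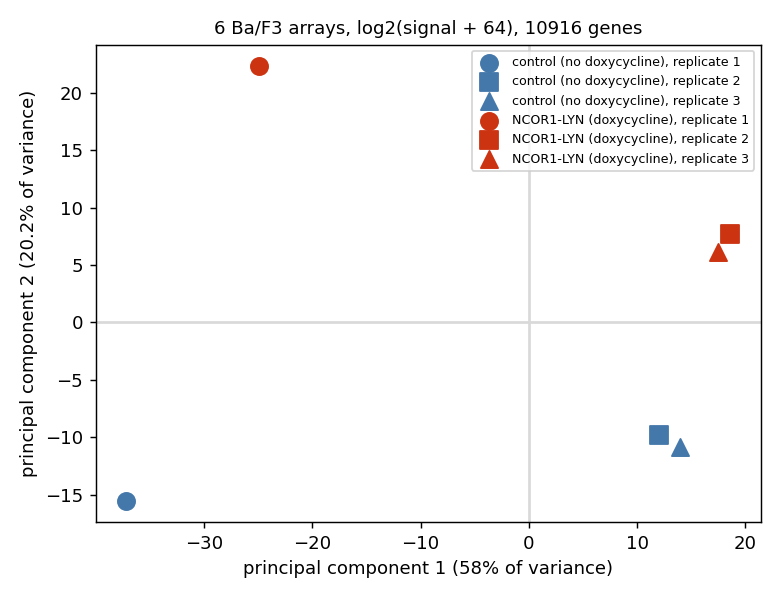
Positions of the 6 arrays on the first 2 principal components of log2(signal + 64), with the share of variance in percent on each axis label; colour marks the group and symbol the replicate number. The replicate 1 arrays sit at −37.2 and −24.9 on component 1, and on component 2 the 3 NCOR1-LYN arrays lie at 6.1 to 22.3 and the 3 controls at −15.5 to −9.8.

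The comparison of NCOR1-LYN with control cells asked which genes and pathways changed when doxycycline was given to induce the fusion. Without a block, 9 genes passed the threshold in limma, 6 higher and 3 lower with NCOR1-LYN, all of them by at least 2-fold. Ltf, which encodes the neutrophil granule protein lactoferrin, rose from a signal of 60.8 ± 24.1 to 567 ± 80.8 (SD, n = 3), a log2 fold change of 2.35 ± 0.19 (SE). The chemokine genes Ccl6 and Ccl9 rose by 1.87 ± 0.13 and 1.15 ± 0.13 on the log2 scale, Ccl6 from 1422 ± 165 to 5367 ± 439. Ccr1, which encodes a chemokine receptor, fell from 1274 ± 553 to 148 ± 42.9, a log2 fold change of −2.60 ± 0.29. Osm, the gene of the cytokine oncostatin M and a target of STAT5, rose from 619 ± 23.8 to 1454 ± 133, a log2 fold change of 1.15 ± 0.13. Ston2, an adaptor of endocytosis, and the membrane protein gene Plxdc1 also rose, with log2 fold changes of 2.03 ± 0.17 and 1.31 ± 0.14, while a dimmer second probe set of Plxdc1 had −0.38 (unadjusted p = 0.187). The mucin gene Muc20 fell, with a log2 fold change of −1.71 ± 0.16, and so did S100a6, which encodes a calcium-binding protein, with −1.44 ± 0.13. Adjusted p in limma ran from 0.0136 for Ccl6 to 0.0412 for Ccr1, Osm, Ccl9 and Plxdc1. All 9 genes also passed with the replicate block, with adjusted p from 0.00151 to 0.0165. In limma, leaving out control 2, control 3, NCOR1-LYN 2 or NCOR1-LYN 3 left 0 genes past the threshold. In those limma fits 345 to 408 genes had an unadjusted p under 0.05, against 519 with all arrays. These 519 are a smaller share of the 10916 genes than the 0.05 expected if nothing changed. The fit without a block thus held no excess of small p-values. Without control 1, 15 genes passed, and 12 without NCOR1-LYN 1. Without the filter on dim genes, or with it at the 60th percentile, 1 gene passed, Ccl6.

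**Figure D2:**
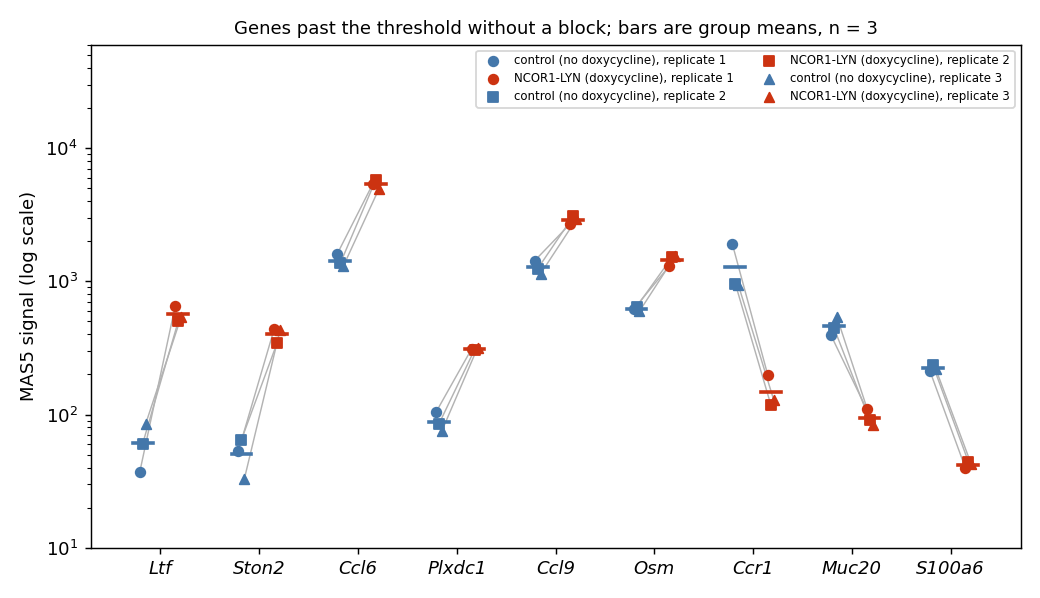
MAS5 signal on a logarithmic axis for the 9 genes past the threshold without a block, with 1 point per array, bars at the group means (n = 3) and grey lines joining arrays of the same replicate number. In every gene the 3 NCOR1-LYN arrays lie all above or all below the 3 controls, as for Ccr1, with means of 1274 and 148. The rule for these genes asked for this, so it adds no evidence. Of all genes tested, 11.2% had groups that did not overlap, against 10% expected by chance.

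With the replicate number as a block, 90 genes passed in limma, 29 higher and 61 lower with NCOR1-LYN, and 46 of them changed at least 2-fold (19 higher and 27 lower). The genes of this paragraph were chosen after their values were seen, by a rule of size on the blocked fit or, for Cish, the rule for lists. This rule of size asked for the same direction in all 3 pairs in place of groups that did not overlap. Pim2, a serine/threonine kinase gene induced through STAT5, rose, with a log2 fold change of 1.87 ± 0.10 (SE in the blocked fit) and signals of 1515 ± 937 and 5619 ± 3250 (SD, n = 3, as for the signals below). Cish, a STAT5 target that dampens cytokine receptor signalling, rose by 1.21 ± 0.15. Epx (eosinophil peroxidase) rose by 1.59 ± 0.13 and Lyz1 (lysozyme) by 1.30 ± 0.15, and for Pim2, Epx and Lyz1 the signals of the groups overlapped. Dimmer probe sets of Lyz1 had log2 fold changes of 0.885 (mean signal 164) and 0.15 (mean signal 25, near the floor). Aldh1a1, a retinaldehyde dehydrogenase gene, rose from a signal of 15.5 ± 10.4 to 790 ± 708, with 1607, 349 and 415 in NCOR1-LYN replicates 1, 2 and 3. Its near-identical paralogue Aldh1a7 rose from 29.8 ± 16.7 to 236 ± 56.5, so their probes can share signal. S100a4, a calcium-binding protein gene, fell from 8513 ± 592 to 979 ± 574, a log2 fold change of −3.26 ± 0.31. The chemokine receptor gene Cxcr2 fell from 384 ± 229 to 43.5 ± 51.6, with 103, 13.4 and 14 in NCOR1-LYN replicates 1, 2 and 3. The membrane metalloprotease gene Adam8 fell from 1148 ± 271 to 339 ± 81.7, the mast cell chymase gene Cma1 from 330 ± 246 to 46.2 ± 37.7 and Padi2, which encodes an enzyme that citrullinates proteins, from 478 ± 179 to 102 ± 33.9. Adjusted p of these genes ran from 0.00151 (Pim2) to 0.0297 (Aldh1a1) with the block and from 0.0637 (Aldh1a7) to 0.999 (Epx and Lyz1) without it. They are a choice among the genes of the rule of size. The rule also gave Lonrf1 (1.72), Ces5a (1.61) and St8sia4 (1.23) as higher on the log2 scale. As lower it also gave Rab19 (−2.10), the aldehyde dehydrogenase gene Aldh3a1 (−1.69), Oosp1 (−1.46) and Greb1 (−1.44). Of the 41 blocked calls with a second probe set above the filter (a signal of about 47), 40 moved the same way in it (97.6%, exact 95% interval 87.1 to 99.9%). A second probe set reads the same RNA on the same arrays, so it says nothing of the spread between cultures. With both replicate 1 arrays left out, which was tried after the data were seen, 744 genes passed in limma, 347 higher and 397 lower. That fit held only 2 arrays per group, which correlated at 0.994 in controls and 0.993 with NCOR1-LYN, so its count rests on the small spread between close arrays. The blocked fit rests on 2 residual degrees of freedom, and on simulated data 19.5 of its 195.5 calls per run were false. The simulated changes were the same in all 3 pairs, while in these arrays 1314 genes changed differently in the replicate 1 pair. The simulated share of false calls may therefore not hold for the real 90 genes.

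The measured genes of the list of fusion partners and SRC family genes and the receptors for interleukin 3 and related cytokines gave 0 calls with all arrays, over all genes, with or without the block. Of the former list, 3 members were measured, too few for a list test, and Csk, Fgr and Fyn had log2 fold changes of −0.15 ± 0.25, 0.08 ± 0.18 and 0.06 ± 0.35 (SE). Csk is not itself a SRC family kinase, and Fgr lay near background (signals of 46.25 in control and 53.24 in NCOR1-LYN cells). For the SRC family kinases themselves the result thus rests on Fyn. The 6 measured cytokine receptor genes did not pass either. Csf2rb, the common beta chain of the interleukin 3 receptor, had pairwise log2 changes of −0.68, 0.68 and 1.07 in replicates 1, 2 and 3, and its near-identical paralogue Csf2rb2 of −1.02, 0.74 and 0.96. Il3ra, the alpha chain, had a log2 fold change of 0.09 ± 0.25, Crlf2 0.29 ± 0.38, Il4ra 0.17 ± 0.19 and Il2ra −0.56 ± 0.60. Adjusted over the list alone, 0 receptors passed without and 1 with the block (Il2ra, lower, with a log2 fold change of −0.20 in its second probe set). As a list, the receptors had an adjusted p of 0.279 in camera, limma's test of a list against all other genes, 0.411 with the block, 0.00236 without both replicate 1 arrays and 0.00939 with array weights (median 0.36). The weights of the replicate 1 arrays were low (0.161 and 0.209), so the last 2 fits are not separate support. Without both replicate 1 arrays, which left 2 arrays per group and was tried after the data were seen, 4 receptors passed over all genes, Csf2rb (0.87, adjusted p = 0.00056), Csf2rb2 (0.85, 9.06e-05) and Il4ra (0.41, 0.0199) as higher and Il2ra (−0.41, 0.0456) as lower.

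Targets of STAT5, the transcription factor activated by interleukin 3, went both ways. Of 19 measured genes, 1 rose (Osm) and 0 fell, 1 passed when adjusted over the list alone, and with the block 3 rose (Pim2, Cish and Osm) and 16 did not pass. With the block, 7 passed when adjusted over the list alone, 5 higher and 2 lower. The list's median log2 fold change was −0.05 and its mean 0.21, its test pointed upward, and these signs differ (camera adjusted p = 0.132). Lif, a cytokine gene chosen after its values were seen, had pairwise log2 changes of 0.00, 1.09 and 1.30. The adaptors and negative regulators of SRC kinases (26 measured, 0 calls over all genes or adjusted over the list alone, median −0.05) had an adjusted p of 0.54, and Lat2 had the largest change among them, −0.79 ± 0.31. Its pairwise changes were −1.72, −0.41 and −0.24 in replicates 1, 2 and 3, so its size came mostly from the replicate 1 pair.

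The list of feedback and immediate early genes of the ERK pathway stood lower with NCOR1-LYN, with 16 of 21 measured genes below 0 and members going both ways. Without a block 0 passed over all genes, 1 (Egr3, chosen after its values were seen) passed when adjusted over the list alone, and Egr3 fell with the block, with a log2 fold change of −1.33 ± 0.18 (adjusted p = 0.0288). A second Egr3 probe set, with a mean signal of 111 against 174, had a log2 fold change of −0.20 (unadjusted p = 0.268 with the block). The list's median log2 fold change was −0.27 (camera adjusted p = 0.00351, and 0.00973 with the block), with adjusted p = 0.614 with an estimated correlation. The medians of the pairs were −0.06, −0.30 and −0.47 for replicates 1, 2 and 3. The difference of the replicate 1 pair from the others passed a camera test chosen after the data were seen (adjusted p = 0.00103). That test was run only at the preset correlation of 0.01, with the spread taken from replicates 2 and 3 alone. Etv5, a transcription factor gene of this pathway, had pairwise changes of −0.10, −2.17 and −2.48, and the phosphatase gene Dusp4, chosen after its values were seen, of −0.21, −1.95 and −1.86. Adjusted over the list alone, 10 passed with the block, 7 lower and 3 higher, the 3 being Myc, Jun and Phlda1, chosen after their values were seen. Phlda1 had pairwise changes of 0.00, 1.79 and 1.81, Jun of 1.29, 0.71 and 0.44 and Myc of 0.49, 0.53 and 0.29. In fry the ERK list had an adjusted p of 0.332 without and 0.441 with the block. Genes induced by FOXO factors (12 measured, median −0.16) did not pass as a list (adjusted p = 0.132), and 0 of them passed without a block, also when adjusted over the list alone, as was so for p53 targets. With the block 1 FOXO target, Txnip, fell, with a log2 fold change of −0.67 ± 0.09 (adjusted p = 0.0281). When adjusted over the list alone, 5 FOXO targets passed with the block, 1 higher and 4 lower. Genes induced by p53 (19 measured, median −0.25) had a camera adjusted p of 0.061 without and 4.6e-04 with the block, with adjusted p = 0.537 with an estimated correlation and the block. Trp53inp1 fell with the block by 0.78 ± 0.10 on the log2 scale (adjusted p = 0.0281). With the block, 3 p53 targets passed when adjusted over the list alone, 1 higher and 2 lower. The p53 list had a median of 0.03 without control 1 (adjusted p = 0.988), −0.08 without NCOR1-LYN 2 (0.385) and −0.11 without NCOR1-LYN 3 (0.556), and passed without control 2 (−0.44, adjusted p = 0.00583), control 3 (−0.42, 0.00595) or NCOR1-LYN 1 (−0.58, 3.59e-05), with array weights (−0.24, 0.00981) and without both replicate 1 arrays (−0.26, 0.000117). For the p53 list, array weights and leaving out both replicate 1 arrays are not separate support, since the weights of replicate 1 were low. The FOXO list passed without control 2 (−0.30, adjusted p = 0.0476) or control 3 (−0.29, 0.0232) and had a median of −0.02 without control 1.

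The lists of the interferon response and of NF-kB targets stood lower with NCOR1-LYN, with negative medians in all 3 pairs. Of 19 measured interferon response genes, 15 had negative changes in every pair and the list's median log2 fold change was −0.42, with pair medians of −0.58, −0.33 and −0.25 (camera adjusted p = 6.8e-06, and 7.11e-10 with the block). The call was lost with an estimated correlation between genes (adjusted p = 0.626 with an estimated correlation). In fry the list had an adjusted p of 0.73 without and 0.0788 with the block. Without control 1 the median was −0.16 (camera adjusted p = 0.0274). Of its members 0 passed without a block, also when adjusted over the list alone, and with the block 1 fell, Usp18, which encodes a protease that restrains interferon signalling, with a log2 fold change of −1.54 ± 0.13 (adjusted p = 0.00692). Adjusted over the list alone, 9 fell with the block, among them the interferon regulator Irf7 (−0.80 ± 0.14) and the RNA sensor gene Ddx58 (−0.73 ± 0.12), both chosen after their values were seen. The interferon list also moved with the replicate number, since 13 of its 19 genes were higher in replicate 1 of both groups. The NF-kB target list (16 measured) had a median of −0.28 and pair medians of −0.24, −0.26 and −0.23 (camera adjusted p = 5.57e-05, and 4.6e-04 with the block), with adjusted p = 0.518 with an estimated correlation. In fry, which tests whether the genes of a list move one way on balance, it had an adjusted p of 0.107 without and 0.00367 with the block. Its inhibitor gene Nfkbia had a log2 fold change of −0.72 ± 0.19 and Tnip1, chosen after its values were seen, −0.46 ± 0.14. Both passed with the block when adjusted over the list alone, and 0 NF-kB targets passed over all genes.

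The list of myeloid markers stood higher with NCOR1-LYN through some of its genes, since 7 of 13 measured genes had positive and 6 negative changes. Over all genes 1 rose (Ltf) and 0 fell, 3 rose when adjusted over the list alone (Ltf, Ngp and Prtn3), and with the block 2 rose (Ltf and Lyz1), or 6 rose and 1 fell when adjusted over the list alone. Ngp, a neutrophilic granule protein gene, went from a signal of 822 ± 582 to 4439 ± 291 (SD, n = 3), and Prtn3, which encodes proteinase 3, from 1195 ± 492 to 3618 ± 1638 (both chosen after their values were seen). The list's median log2 fold change was 0.37 (camera adjusted p = 0.0184, and 0.0104 with the block), with adjusted p = 0.518 with an estimated correlation, and adjusted p of 0.107 in fry, or 0.0733 with the block. The list did not pass without NCOR1-LYN 1 (median 0.02, adjusted p = 0.118), without the filter (−0.003, 0.124), with the filter at the 60th percentile (0.37, 0.0627), with an offset 4 times larger (0.13, 0.0728), with the mean of all probe sets (0.10, 0.114) or with array weights (0.08, 0.124). Its median was 0.10 without control 1 (adjusted p = 0.034). The macrophage marker Cd68, chosen after its values were seen, went the other way, with −0.67 ± 0.22, and passed as lower with the block only when adjusted over the list alone. Mast cell and basophil markers did not pass as a list (6 measured, median −0.20, adjusted p = 0.161), and went both ways. With adjustment over the list alone 3 passed, Fcer1a, the alpha chain of the IgE receptor (2.40 ± 0.47), the transcription factor gene Gata2 (−0.80 ± 0.26) and Cma1, which also fell with the block (Gata2 and Cma1 chosen after their values were seen). Lists of B lymphoid (8 measured, adjusted p = 0.62), erythroid and megakaryocyte (7, adjusted p = 0.25) and T and NK cell markers (6, adjusted p = 0.721) did not pass, with medians of −0.08, −0.19 and −0.18. The largest changes among their genes were −0.50 ± 0.20 for Cd72, −0.71 ± 0.21 for Gp9 and 0.81 ± 0.31 for Nkg7. Adjusted over the list alone, 0 genes of these 3 lists passed without a block. With the block, 4 erythroid and megakaryocyte genes passed in this way, 1 higher and 3 lower (Gp9 among them). So did 2 T and NK cell genes, 1 higher (Nkg7) and 1 lower, and 0 B lymphoid genes did. Of the fibroblast markers 4 were measured, too few for a list test, and 2 passed as lower when adjusted over the list alone, among them Col5a1 with a log2 fold change of −0.65 ± 0.20, and 3 as lower with the block.

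The list of the NCOR and HDAC3 corepressor complex and its nuclear receptor partners stood slightly higher, with 7 of 10 measured genes above 0. It had a median log2 fold change of 0.18 and pair medians of 0.22, 0.19 and 0.21 (camera adjusted p = 0.00351, and 0.0151 with the block), with adjusted p = 0.614 with an estimated correlation. In fry its adjusted p was 0.332 without and 0.0327 with the block. Of its genes 0 passed over all genes, and 3 rose when adjusted over the list alone, the histone deacetylase gene Hdac7 (0.72 ± 0.14), the complex member Tbl1xr1 (0.44 ± 0.11) and the retinoic acid receptor gene Rara (0.61 ± 0.19), the last 2 chosen after their values were seen. The nuclear receptor gene Nr1d2 (−0.46 ± 0.14, SE in the blocked fit), chosen after its values were seen, passed as lower with the block when adjusted over the list alone. The list did not pass without NCOR1-LYN 1 (adjusted p = 0.0507) or without the filter on dim genes (median 0.14, adjusted p = 0.0805).

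Among stress and growth lists the ATF4 amino acid response passed, and its change came from the replicate 1 pair. Its 36 measured genes had a median log2 fold change of 0.12 (camera adjusted p = 0.0114, and 0.00679 with the block), with adjusted p = 0.805 with an estimated correlation, adjusted p of 0.786 in fry (0.796 with the block), and 0 genes past the threshold over all genes or adjusted over the list alone. The pair medians were 0.65, −0.05 and −0.06 for replicates 1, 2 and 3, and the difference of the replicate 1 pair from the others had a camera adjusted p of 3.12e-15. That test was run only at the preset correlation of 0.01 and took the spread from replicates 2 and 3 alone, so this p overstates the certainty about a single pair. Without both replicate 1 arrays the list stood lower, with a median of −0.11 (adjusted p = 0.0432). Its stress regulator genes Ddit3 and Trib3, chosen after their values were seen, had pairwise log2 changes of 1.89, −0.40 and −0.58 and of 2.09, 0.00 and −0.29. The ER stress list (20 measured, median 0.02, adjusted p = 0.65) and the heat shock list (12 measured, median 0.01, adjusted p = 0.989) did not pass, with 0 genes adjusted over the list alone. Without control 1 the ATF4 list had a median of −0.08 (adjusted p = 0.224) and the ER stress list −0.17 (adjusted p = 0.0299), and without NCOR1-LYN 1 the adjusted p of the ATF4 list was 0.143. It was also lost without the filter (0.0563) and with array weights (median −0.09, adjusted p = 0.194), and its median was 0.24 without control 2 and 0.25 without control 3.

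Proliferation and metabolic lists did not pass in camera without the block. Cholesterol synthesis (20 measured, median 0.21) and oxidative phosphorylation (47 measured, median 0.05) had camera adjusted p of 0.102 and 0.061 without the block and of 0.00136 and 0.0104 with it, the blocked calls being lost with an estimated correlation (adjusted p = 0.61 and 0.743). The cholesterol median was −0.17 without control 1 (adjusted p = 0.136) and −0.005 without NCOR1-LYN 3 (0.88), against 0.46 without control 2 (0.00139) or control 3 (0.00129) and 0.50 without NCOR1-LYN 1 (0.000197). Oxidative phosphorylation passed without control 2 (0.13, adjusted p = 0.000696), control 3 (0.12, 0.00327) or NCOR1-LYN 1 (0.17, 3.44e-05), with quantile normalization (0.06, 0.0119) and without both replicate 1 arrays (0.04, 0.0432). The lists of MYC and ribosome biogenesis targets (27 measured, median 0.08, adjusted p = 0.0748), G1/S genes (27, median 0.05, adjusted p = 0.154) and G2/M genes (29, median −0.04, adjusted p = 0.721) did not pass with all arrays. The G2/M list had pair medians of 0.14, −0.18 and −0.06, which differed between the replicate 1 pair and the others (camera adjusted p = 5.29e-05). That test was run only at the preset correlation of 0.01, with the spread taken from replicates 2 and 3 alone. The G2/M list passed as lower without control 1 (median −0.21, adjusted p = 6.86e-06), with array weights (−0.13, 0.00229) and without both replicate 1 arrays (adjusted p = 0.000252). These fits all set control 1 or replicate 1 aside, fully or through low weights, and are not separate support. With all arrays, mitochondrial translation (34, median 0.04, adjusted p = 0.123), glycolysis (17, median −0.04, adjusted p = 0.862), fatty acid synthesis (13, median 0.09, adjusted p = 0.132) and the BCL2 family (11, median −0.20, adjusted p = 0.212) did not pass either. Of the members of these 9 lists 0 passed without a block, also when adjusted over the list alone, and 1 passed with it, the mitochondrial ribosomal protein gene Mrpl16, which fell by 0.60 ± 0.09 on the log2 scale (adjusted p = 0.0354). With the block, 3 passed when adjusted over the list alone, all lower. These were Mrpl16 and 2 BCL2 family genes. Hypoxia targets had a median of −0.12 and a mean of −0.02 while the test pointed upward (16 measured, adjusted p = 0.76), and their member Bhlhe40, a transcription factor gene, rose with the block by 0.91 ± 0.10 (adjusted p = 0.0197). Of the hypoxia targets 1, Bhlhe40, passed without and 2 with the block when adjusted over the list alone, all higher. In all, 6 of 27 lists passed in camera, 3 higher and 3 lower, 9 passed with the block, and 0 passed with an estimated correlation in either fit. Single arrays also decided other lists, in that G1/S genes passed as higher without control 2 (adjusted p = 0.0139), control 3 (0.00595) or NCOR1-LYN 1 (0.014). MYC targets passed without NCOR1-LYN 2 (0.0353) or NCOR1-LYN 3 (0.000418) or with quantile normalization (0.0434). Mitochondrial translation passed without control 2 (0.0139) or control 3 (0.0232). Fatty acid synthesis passed without control 2 (0.038) or NCOR1-LYN 1 (0.0272), STAT5 targets without control 2 (0.0476) or control 3 (0.0331), glycolysis as lower without control 1 (0.0159), erythroid markers as lower without control 2 (0.0476) and the cytokine receptors without control 1 (0.0488). The count of lists came to 15 without control 2, 13 without control 3, 9 without control 1, 8 without NCOR1-LYN 1 and 7 without NCOR1-LYN 2 or NCOR1-LYN 3.

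**Figure D3:**
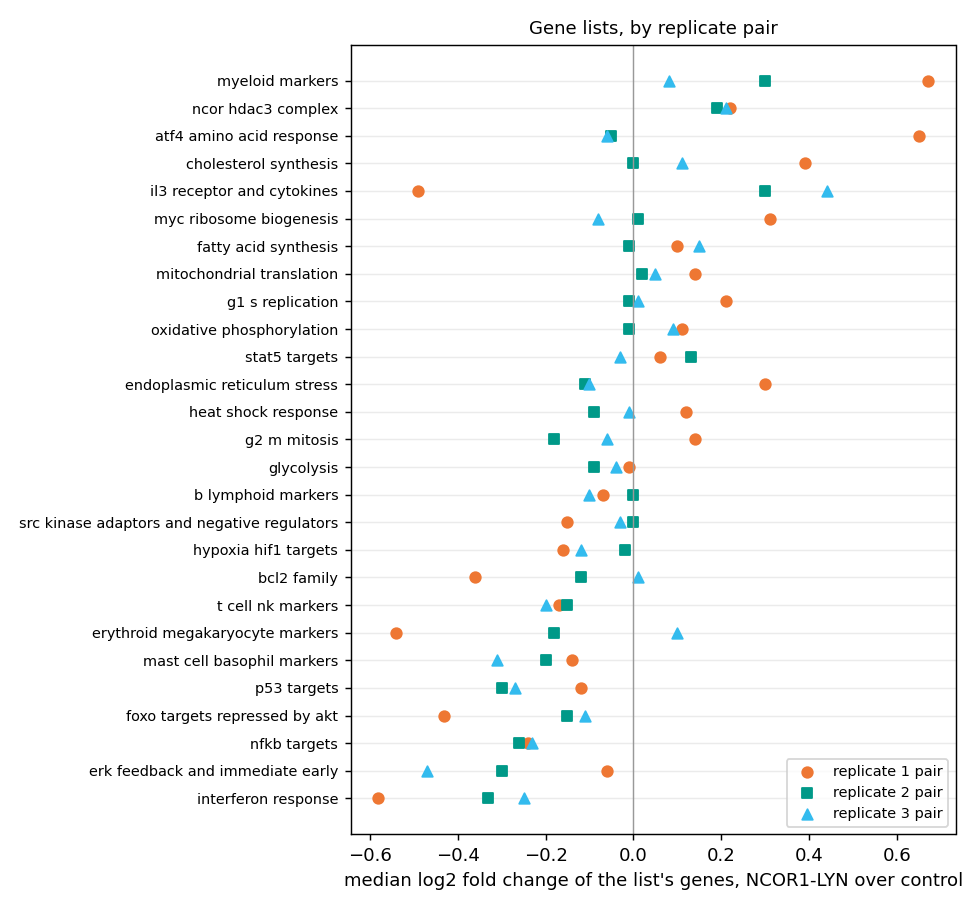
Median log2 fold change of the measured genes of 27 lists, NCOR1-LYN over control, with 1 symbol per replicate pair. The 3 pairs lie close together for the NF-kB targets (−0.24, −0.26 and −0.23), while the amino acid response stands at 0.65 in the replicate 1 pair and at −0.05 and −0.06 in the others.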

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

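The test of whether the replicate 1 pair differed, the genes named for it, the comparison of replicate 1 with the other replicates, the test of RNA degradation and the look at doxycycline itself were chosen after the results were seen.

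For 1314 genes the change with NCOR1-LYN differed between the replicate 1 pair and the other pairs at an adjusted p under 0.05 in limma (interaction term, 2966 at an unadjusted p under 0.05). This difference between pairs was found with 2 residual degrees of freedom, so the spread came only from replicates 2 and 3. Among these genes 1136 changed more in size in the replicate 1 pair and 904 had the opposite sign there. The genes were picked because a single pair differed from the mean of the others, and this choice favours both counts. The counts therefore say little about the genes themselves. Csrp3 had a log2 change of −2.43 in the replicate 1 pair and a mean of 2.22 in the others, Ngp 4.27 and 1.94, Prtn3 −0.01 and 2.24, Fcer1a 0.68 and 3.26, Etv5 −0.10 and −2.33, and Ddit3 1.89 and −0.49. Across genes, the pairwise changes correlated at 0.49 between replicates 2 and 3, at 0.23 between 1 and 2 and at 0.21 between 1 and 3, and genes are not independent replicates.

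The replicate 1 arrays of both groups stood apart from the others, and technical explanations were weighed for this pattern. Degraded RNA is argued against, since the 3′ to 5′ ratio of beta-actin was at most 1.168 in the replicate 1 arrays and at least 1.192 in the others, and that of Gapdh was lower too. Array scaling as the whole cause is argued against, since 76.6% of the 3752 genes called between replicate 1 and the others were also called after quantile normalization. Probe-level hybridization stays open, since another probe set moved the same way in 74% of the genes, between the values set in advance for either outcome. A different state of the cultures may also account for it, and no biological explanation was tested because the labels give no culture day or density. The control spikes parted replicate 1 too, with poly-A spikes at 621 and 564 against 334 to 380 in the others. The hybridization spikes stood at 4135 and 4283 against 5174 to 5392. How far labelling or hybridization adds to the pattern was not tested.

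The number of genes past the threshold was set against other splits of the arrays. Of the 10 splits into 3 and 3 arrays, 1 gave as many as the real 9 genes, the real one itself, and the highest of the others gave 0. With the block, 1 of the 4 ways to swap labels within pairs gave as many as the real 90 genes, again the real one, and the highest of the others gave 1. These splits are too few for a share under 0.05.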

How the results depend on the processing

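The fit with replicate 1 as a 2-level batch, the fit without both replicate 1 arrays and the blocked list tests with an estimated correlation or fry were chosen after the data were seen. For genes past the threshold (9, of which 6 higher) counts stayed within 1.5 times without an offset, with quantile normalization (12, 7 higher and 5 lower), median centring (8, 4 higher and 4 lower), the mean of all probe sets, every probe set, no intensity trend or robust variances. They came to 1 without the filter or with it at the 60th percentile (1 at least 2-fold in each, with other numbers of genes tested), and 4 genes were at least 2-fold with an offset 4 times larger. They came to 502 with array weights (81 at least 2-fold), 90 with the replicate block (46), 262 with replicate 1 as a 2-level batch (66) and 744 without both replicate 1 arrays (97), the last with only 2 arrays per group. Array weights gave the replicate 1 arrays only 0.161 and 0.209, so that fit also rests mostly on replicates 2 and 3. Leaving out 1 array gave 0 to 15 genes, 0 to 14 at least 2-fold and 7 to 15 lists. Of the lists, 6 passed, 3 without the filter, 5 with it at the 60th percentile, 0 with an estimated correlation, 0 in fry (0 and 2 in the blocked forms), 9 with the replicate block and 11 without both replicate 1 arrays. The ATF4 list's median turned to −0.092 with array weights and −0.110 without both replicate 1 arrays, and ran from −0.078 (without control 1) to 0.253 with 1 array left out. The ER stress list's turned to −0.107 without both replicate 1 arrays and ran from −0.170 (without control 1) to 0.122 with 1 array left out. Ddit3 turned to −0.49 and Fcgr1 to −0.54 without both replicate 1 arrays. The cause was not tested for these changes, beyond the spread that replicate 1 adds. Among single genes 1817 values kept their side of the threshold, 203 passed it newly, 62 no longer passed, 31 changed sign without passing in either setting and 2 reversed. Among lists, judged by the direction of the list test, which can differ from the sign of the median, these were 527, 41, 35, 36 and 5. The replicate block changed list calls for p53 targets, oxidative phosphorylation and cholesterol synthesis and for no other list in camera. With an offset 4 times larger the medians shrank to −0.269 for the interferon, −0.168 for the NF-kB and −0.175 for the ERK list, which still passed in camera. Signals close to background limit dim genes, since over 50% of the probe sets lay below 64.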

Other observations

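The comparison of replicate 1 with the other replicates, its genes and the look at doxycycline itself were chosen after the data were seen.

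In replicate 1 of both groups, signals of sterol synthesis and cell division genes were lower and those of p53 targets higher than in replicates 2 and 3. In limma with the group as a covariate (2 against 4 arrays), 3752 genes passed, 2121 higher and 1631 lower in replicate 1, and 351 of them differed at least 2-fold. Of 20 cholesterol synthesis genes 17 were lower and 0 higher, with a median log2 difference of −0.96, and Cyp51, which encodes the lanosterol demethylase, had a mean signal of 549 against 2083. Of 29 G2/M genes 18 were lower, of 27 G1/S genes 14, of 47 oxidative phosphorylation genes 28 and of 17 glycolysis genes 10. Of 19 p53 targets 13 were higher, with a median of 0.82, and of 19 interferon response genes 13 were higher, with a median of 0.61. The camera adjusted p was 4.61e-10 for cholesterol synthesis, 2.48e-06 for p53 targets and 7.34e-05 for the interferon response, with adjusted p = 0.416, 0.315 and 0.416 with an estimated correlation. For G2/M genes it was 2.63e-07 and for G1/S genes 1.78e-05, with adjusted p = 0.462 and 0.456 with an estimated correlation. Oxidative phosphorylation had a camera adjusted p of 6.61e-09 and glycolysis of 4.16e-05, with adjusted p = 0.416 for each with an estimated correlation. Bnip3, a mitophagy receptor gene induced by hypoxia, had a log2 difference of −2.67 ± 0.13 (SE), the cytokine gene Il6 −2.15 ± 0.21, Epx −2.74 ± 0.12, Pim2 −2.02 ± 0.08, Gzmb 2.72 ± 0.19 and the actin regulator gene Avil 3.47 ± 0.50. The array's own control probe set for the transferrin receptor gave signals of 222 and 279 in replicate 1 and of 1248 to 1427 in the other arrays. The poly-A control spikes gave 621 and 564 in replicate 1 and 334 to 380 in the others.

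Some granule protein genes (Ltf, Epx and Lyz1, and Ngp and Prtn3 by their list alone) were higher with NCOR1-LYN while others were not, and mature neutrophils among the cells were weighed as a source. S100a8 and S100a9, which neutrophils express abundantly, went from 89.0 ± 71.4 to 18.3 ± 14.9 and from 105 ± 87.2 to 65.5 ± 21.9 (SD, n = 3), while S100a9 had pairwise log2 changes of 1.06, −0.71 and −1.05 in replicates 1, 2 and 3 and Lcn2, another neutrophil gene, chosen after its values were seen, of 3.65, 0.08 and −0.22, against 4.27, 1.89 and 1.98 for Ngp. The upper limit of the gain of S100a8 and S100a9 was 1.8% of the gain of Ngp, and the bound of 10% set beforehand was met, yet it set signals of different probe sets against each other near the floor of the arrays and so decides nothing. Other neutrophil genes, also chosen after their values were seen, went both ways and do not settle the question. Pairwise changes were −2.09, −1.98 and −2.06 for the receptor gene Cxcr2 and −0.77, −0.61 and −0.46 for Mmp9 (321 ± 114 to 184 ± 47.0). Mean signals rose for Mmp8 (7.59 ± 6.37 to 42.1 ± 29.0) and Lyz2 (231 ± 125 to 366 ± 252). Camp (9.60 to 11.5), Cd177 (16.5 to 23), Elane (37.8 to 51.3) and Ctsg (9.19 to 5.42) stayed near the floor, where they decide nothing. Lower signals from the Ba/F3 cells may hide a small gain, so mature neutrophils stay open, immature granulocytic cells were not tested, and doxycycline itself stays open too, since the amino acid response list, with a median log2 fold change of 0.12 (0.121), cannot separate the drug from the fusion.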
